A study of Rattus norvegicus with 6 samples.

How the data were processed

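RNA from primary rat Schwann cells with inducible RafER was hybridised to Affymetrix rat expression arrays, 3 after vehicle and 3 after 24 h of tamoxifen. Total RNA was extracted with a Qiagen RNeasy kit, per the labels' protocols. The deposited values are log2 expression values per probe set, and RMA, which corrects background, normalises between arrays and summarises probes, is named in the submitters' processing notes, with no version given in the sources used here. The values ran from 2.99 to 14.58, and the sorted columns of any 2 arrays differed by at most 0.30 log2 units. RMA compresses low values, so folds of dim genes tend to be understated. The file holds no detection calls, so a low level can be background. The number of arrays limits the precision.

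The table held 31099 probe sets, of which 57 are manufacturer controls and were left out of the tests. Of all probe sets, 20826 were listed with 1 gene symbol, 436 were listed with several, and 9780 were not listed with a gene in the annotation used here. The Entrez identifiers of 20758 matched the RefSeq gene table (assembly GRCr8), and 0 symbols changed. Probe sets with several symbols were not named. Each of 14217 genes was represented by its probe set of highest mean log2 value over all 6 arrays. No genome was used, so no coordinates are given.

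Groups were taken from the sample descriptions. The source labels name treated animals where the design text has treatment of cultured cells, and the design text was followed. Tamoxifen was compared with vehicle with lmFit and eBayes of limma 3.58.1 in R 4.3.3, a two-sided moderated test on all 6 arrays without covariates, with Benjamini-Hochberg adjustment over 31042 probe sets and a threshold of 0.05. Fold changes are log2 differences, tamoxifen minus vehicle, with the standard error of the model. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so none was used. Gene lists were tested with limma's camera at its preset correlation of 0.01 on 1 probe set per gene, adjusted over the 27 lists (22 of pathways and cell states, 5 of markers of other cell types). Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also uses the few residual degrees of freedom of the arrays in place of those of the genes. A call lost there need not come from correlation between members. Of 696 listed genes 617 were measured.

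The lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap. Genes whose symbol is a LOC or RGD number were left out of this ranking. The rule also names up to 4 members past the threshold with the largest change from each list. To these it adds 16 fixed genes, and up to 2 of the brightest markers from each other cell type. It gave 119 genes, and 3 of the 16 fixed genes were not analysed here. Of 52 named genes with several probe sets, 0 had a probe set past the threshold in the opposite direction. Of 50 such genes past the threshold, 16 had another probe set that did not pass.

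The experiment numbers in the sample titles were checked as pairs. After subtraction of group means, the correlations of arrays with the same number were 0.26, 0.20 and 0.28. Those of arrays with different numbers were all below 0. The subtraction itself pushes these below 0 once the same-number values are above 0, so they add no evidence. With so few arrays such a match can also arise by chance, so the values do not establish that the numbers pair the samples. The fit with the experiment as a block was an alternative. Other alternatives were leaving out each array, other scalings between arrays, a filter on dim probe sets, other variance models and array weights. The mean of a gene's probe sets, leaving out probe sets with the suffix _s_at, _x_at or _a_at, and a minimum fold were also used. An analysis without both arrays numbered 1 and one with the 3' minus 5' difference as a covariate were added after seeing the data.

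The procedure was tested on simulated data with the spread of these arrays, with 200 of 31042 probe sets changed in each of 10 simulations of the tamoxifen comparison. It recovered 12% of changes of 0.5 log2 units, 66.8% of 1, 92.8% of 2 and 98.8% of 4, and 3.91% of its calls were false. Of simulated lists, 10 of 10 raised lists and 1 of 200 unchanged lists were called. Probe sets were simulated independently and lists drawn at random, so these shares hold only where members are uncorrelated. Far fewer probe sets were changed than the 7578 called in the data.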

Results

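Messenger RNA levels were measured on 6 oligonucleotide arrays of cultured primary rat Schwann cells, the glial cells that ensheathe and myelinate the axons of peripheral nerves, here taken from sciatic nerve. The cells carried RafER, a fusion of the kinase Raf with the hormone-binding part of the estrogen receptor, which makes the kinase inducible by tamoxifen. In 3 experiments, which the series' design text calls independent, cells kept in a minimal medium received either the ethanol vehicle or tamoxifen for 24 h, giving 3 vehicle and 3 tamoxifen arrays. The sample source labels speak of treated animals, while the design text places the treatment in culture. The design text was followed here, and what a replicate is rests on it. The p-values of single genes below measure the spread between these samples. List and family p-values at camera's preset correlation compare member genes with other genes and do not measure that spread. The comparison asks how gene expression changes when Raf is activated. Cells without RafER were not analysed here, so an effect of tamoxifen itself and an effect of Raf cannot be told apart. Between arrays of the same group the correlation over probe sets was 0.984 to 0.995, and between arrays of different groups it was 0.934 to 0.966. The vehicle array of experiment 1 had weaker 5' signal than the others: its mean 3' minus 5' difference over 3 rat control transcripts was 0.84 log2 units, against 0.16 to 0.27 on the other 5 arrays.

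**Figure D1:**
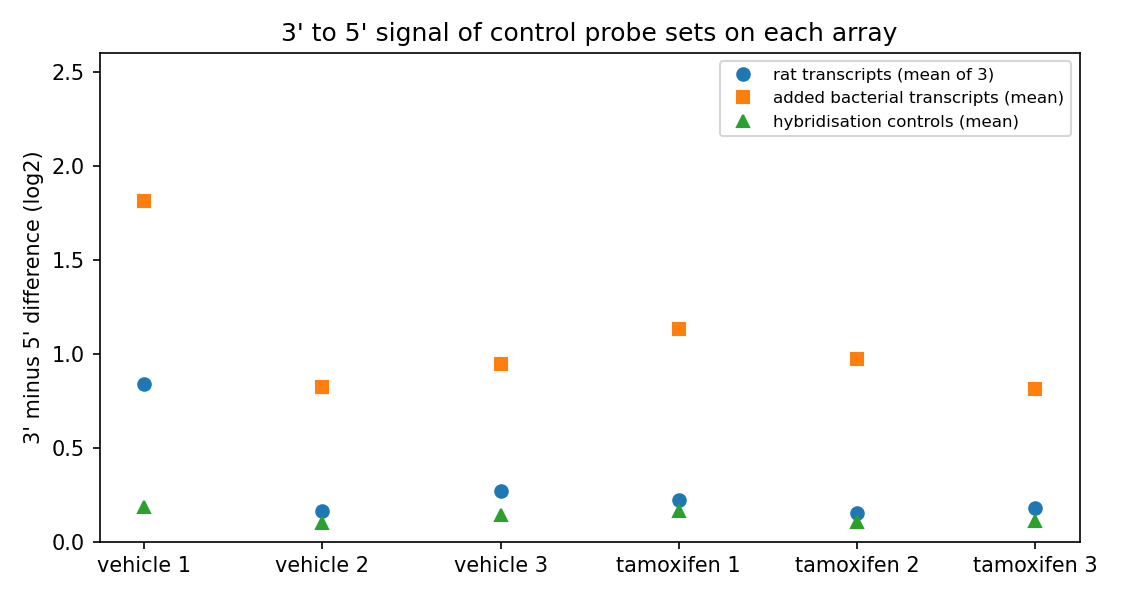
Mean 3' minus 5' difference (log2 units) of the control probe sets on each of the 6 arrays, with 1 point per array for rat transcripts (circles), bacterial transcripts added to the RNA (squares) and hybridisation controls (triangles). The vehicle array of experiment 1 stands above the other 5 for the added transcripts, at 1.81 against 0.81 to 1.13.

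After 24 h of tamoxifen the Schwann cells had higher levels of transcripts that ERK signalling is known to induce (20 of 24 rose) and of genes for DNA replication (26 of 31) and mitosis (29 of 33). Of the cytokine list 7 of 31 rose, of the glucose list 9 of 19 rose, and of the matrix and basal lamina list 14 of 41 fell. These 6 lists passed with camera's preset correlation, but with a correlation estimated from the data only the ERK target list did (adjusted p = 0.0324, against 0.457 for each of the other 5). Transcripts of the myelin proteins Pmp22 and Mbp fell while that of the promyelin transcription factor Egr2 rose. The myelin list as a whole did not pass (camera, adjusted p = 0.868). Of 14217 genes, 4433 (31.2%) passed an adjusted p of 0.05 in the limma test, 1979 of them higher and 2454 lower after tamoxifen. A change of at least 1 log2 unit was found for 813 of the higher and 858 of the lower genes. Among 31042 probe sets, 3574 were higher and 4004 lower. The 3 vehicle and 3 tamoxifen values did not overlap for 6978 genes (49.1%), where chance gives 10% for exchangeable arrays, a share that pairing of the arrays would change. With the unmoderated test 2235 genes passed, and with a test against a fold of 1.5 the number was 883. Without the tamoxifen array of experiment 2, 2668 probe sets were lower.

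**Figure D2:**
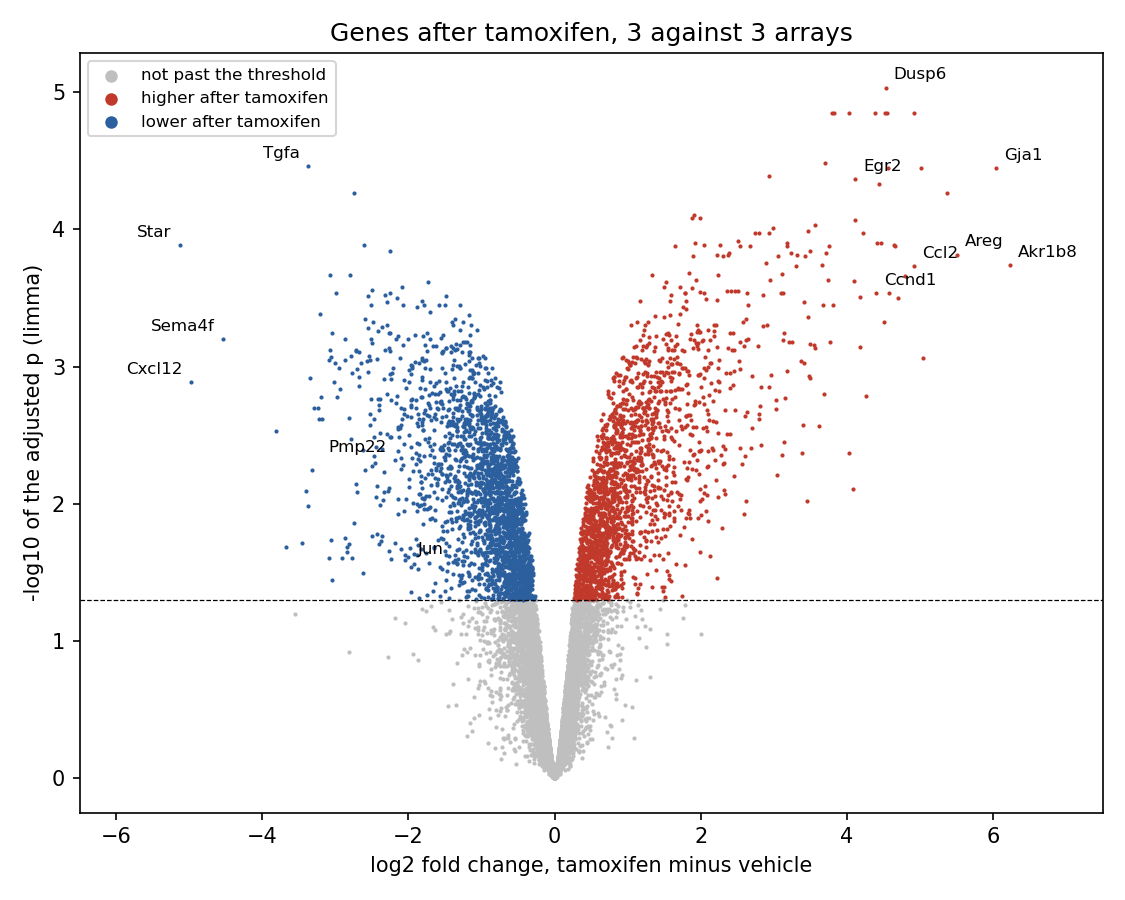
Each point is 1 of 14217 genes, with its log2 fold change (tamoxifen minus vehicle, 3 against 3 arrays) on the x axis and -log10 of its adjusted p on the y axis, and the dashed line marks an adjusted p of 0.05. Red points are the 1979 higher genes, blue points the 2454 lower genes, and Dusp6 stands highest on the y axis.

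Among genes past the threshold whose groups do not overlap, leaving out LOC and RGD numbers, the largest rise was that of Akr1b8, an aldo-keto reductase. It went from 5.93 ± 0.33 to 12.16 ± 0.67 (mean log2 value ± SD, n = 3 arrays per group), a change of 6.23 ± 0.34 (SE). It was followed by Gja1, which encodes the gap junction protein connexin 43 (6.04 ± 0.20 by its brightest probe set, with 3.62 and 0.14 by the other probe sets, the last with adjusted p = 0.344), the EGF receptor ligand gene Areg (5.51 ± 0.29) and the cell surface proteoglycan gene Sdc1 (5.37 ± 0.21, and 3.21 by its dimmer probe set). Pclaf, Mmd, Ccl2, Rftn1, Snhg4, Calca, Igfbp3 and Nptxr rose by between 4.65 and 5.05 log2 units by their brightest probe sets. Other probe sets disagreed for 3 of these: for Rftn1 the other one gave -0.02 (adjusted p = 0.954), for Nptxr 0.06, which did not pass, and for Calca the other ones gave smaller rises of 3.28 and 1.32. At the other end, Star, a cholesterol transport protein of steroid synthesis, fell by 5.13 ± 0.25, from 10.72 ± 0.50 to 5.59 ± 0.19. The chemokine gene Cxcl12 fell by 4.98 ± 0.50 and the semaphorin gene Sema4f fell by 4.53 ± 0.36. Hmcn1, Mlip, Aass, Crispld2, Tgfa, Lims2, Dab1, Txnip and Chrdl2 had changes of -3.82 to -3.29. For Dab1 the other probe sets gave smaller changes of -0.90, -1.09 and -0.10, the last with adjusted p = 0.578. All 24 of these genes moved the same way in all 3 experiments, which the rule that picked them guarantees. The call of Mlip was lost without tamoxifen array 1 (adjusted p = 0.0565), 2 (0.0667) or 3 (0.0700), and that of Aass without vehicle array 2 (0.0599). Leaving out 1 array gave ranges of -4.30 to -2.61 for Mlip, -4.05 to -2.58 for Aass and -3.81 to -2.61 for Lims2.

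Of 24 measured ERK feedback and target transcripts, 20 rose and none fell, with a median log2 fold change of 2.01. The number was the same when p was adjusted over the list alone. Dusp6, a phosphatase that inactivates ERK, went from 8.84 ± 0.03 to 13.37 ± 0.06, a rise of 4.53 ± 0.08 (adjusted p = 9.23e-06). Egr1 rose by 4.51 ± 0.33, the cyclin gene Ccnd1 by 4.40 ± 0.28 and the feedback inhibitor gene Spry4 by 3.19 ± 0.16. Against all other genes the list stood higher (camera, adjusted p = 2.24e-13), and this was the only list whose call held with a correlation estimated from the data (adjusted p = 0.0324 with an estimated correlation).

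Among 16 measured components of the RAS-RAF-ERK pathway itself, 4 rose, 3 fell and 9 did not pass, and the list did not stand apart (adjusted p = 0.716). Adjusted over the list alone, 6 rose and 3 fell. Rasa1, a GTPase-activating protein for RAS, rose by 1.84 ± 0.10 and Nras by 0.95 ± 0.10, while the kinase gene Rps6ka2 fell by 2.65 ± 0.24. Araf showed a difference of -0.07 ± 0.15 (adjusted p = 0.790) by its brighter probe set, and its other probe set was lower (-0.43, adjusted p = 0.0226). Esr1, the gene of the receptor whose hormone-binding part RafER carries, was 0.49 ± 0.11 higher at a low level (5.02 ± 0.13 in vehicle). The Esr1 call was lost without vehicle array 2 (adjusted p = 0.0547), vehicle array 3 (0.0529) or tamoxifen array 3 (0.0554). Whether the probes match the introduced fusion gene is not given in the sources used here.

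The AP-1 and immediate-early transcription factors went both ways: of 22 measured, 5 rose and 6 fell, with 7 and 6 adjusted over the list alone. Fosl1 rose by 3.80 ± 0.10 and Junb by 2.03 ± 0.26, whereas Jun, a driver of the Schwann cell response to nerve injury, fell by 1.40 ± 0.34 from a high level of 13.83 ± 0.10. The median of this list was -0.07, its mean 0.27 and its test direction higher, with an adjusted p of 0.774. The call of Jun was lost without vehicle array 1 (adjusted p = 0.0587), 2 (0.0715) or 3 (0.0582) and without tamoxifen array 2 (0.0625).

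Of 23 measured myelin proteins and promyelin factors, 4 rose and 6 fell, also when adjusted over the list alone, and the list did not stand apart (adjusted p = 0.868). The 2 largest rises were in regulators: Nab2, a cofactor of the Egr transcription factors, rose by 4.56 ± 0.12, and Egr2, which drives myelin gene expression, rose by 4.12 ± 0.15 (1.66 by its dimmer probe set). The structural genes Pmp22 and Mbp fell by 2.18 ± 0.33 and fell by 1.96 ± 0.29, and other probe sets of Mbp gave -1.74 and -1.02. Of 23 immature and injury-associated genes, 4 rose and 8 fell (4 and 10 adjusted over the list alone). The test of this list gave an adjusted p of 0.147, and with the experiment as a block it passed in the lower direction (adjusted p = 0.0257). With an estimated correlation it did not pass (adjusted p = 0.457 with an estimated correlation). Its largest changes were in Id2, which rose by 3.50 ± 0.18 (1.90 by its dimmer probe set), and in Tgfa, which fell by 3.38 ± 0.11. The adhesion gene Cdh2 rose by 1.52 ± 0.24, and of its other probe sets 1 also rose (1.75) and 1 did not pass (0.16, adjusted p = 0.334). Ngfr, the p75 neurotrophin receptor, fell by 1.53 ± 0.32, a call lost without tamoxifen array 2 (adjusted p = 0.0551). Sox2, a transcription factor of immature Schwann cells, fell by 0.89 ± 0.17 by its brightest probe set, while 3 other probe sets (-0.57, -0.32 and 0.04) did not pass. Of 14 general Schwann lineage genes, 1 rose, 2 fell and 11 did not pass (1 and 1 adjusted over the list alone; list adjusted p = 0.868). Tfap2a rose by 0.96 ± 0.15 and Nrcam fell by 0.89 ± 0.14.

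**Figure D3:**
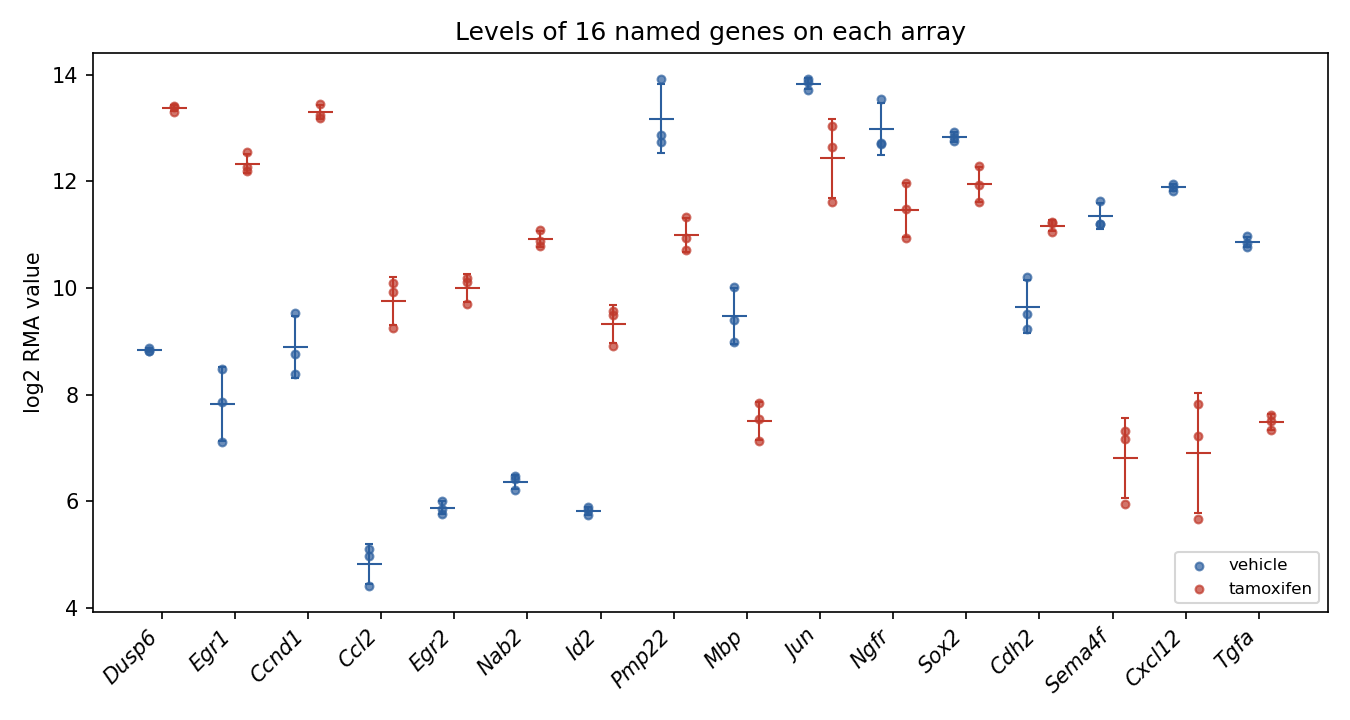
Log2 values of 16 named genes on each array, with points for single arrays, horizontal marks for group means and bars for 1 SD (n = 3, vehicle blue and tamoxifen red). Dusp6 moved from 8.84 to 13.37 with little spread, while Jun stayed above 11 on all arrays and Sema4f and Cxcl12 dropped from above 11 to below 8.

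Among 31 cytokines and chemokines, 7 rose and 2 fell (9 and 2 adjusted over the list alone), and the list passed as higher (adjusted p = 0.0126; adjusted p = 0.457 with an estimated correlation). Ccl2, an attractant of monocytes, rose by 4.92 ± 0.27 from a low level of 4.83 ± 0.38. Il33 rose by 3.45 ± 0.63 and Il11 by 2.28 ± 0.34. Cxcl12 went the other way, as given above. Of 34 growth factors, 9 rose and 6 fell, also when adjusted over the list alone, with no shift of the list (adjusted p = 0.405). Hbegf rose by 3.69 ± 0.40, and Areg and Tgfa, also on this list, are given above. The lymphatic growth factor gene Vegfc rose by 3.41 ± 0.31.

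Axon guidance genes, comprising semaphorins, plexins, ephrins, netrins, slits and their receptors, also split: 10 of 49 rose and 13 fell, with the same numbers adjusted over the list alone. Their median was 0.01, their mean -0.27 and the direction of the test lower (adjusted p = 0.774). Sema4f had the largest fall, followed by the ephrin receptor gene Epha4, which fell by 3.23 ± 0.37 (-4.08, -2.31 and -0.65 by its other probe sets), and the plexin gene Plxna3, which fell by 2.39 ± 0.26. The netrin receptor gene Unc5b rose by 2.62 ± 0.21. Of 39 adhesion receptors 11 rose and 6 fell (13 and 7 adjusted over the list alone; list adjusted p = 0.386). Alcam rose by 3.62 ± 0.46 and Itga8 by 2.41 ± 0.32, while Itgb4, a laminin receptor subunit, fell by 2.47 ± 0.37.

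Extracellular matrix and basal lamina genes were lower as a list (14 of 41 fell and 4 rose; 18 and 4 adjusted over the list alone; median -0.46; adjusted p = 0.0126; adjusted p = 0.457 with an estimated correlation). The basal lamina gene Nid2 fell by 2.81 ± 0.16, Col1a1 fell by 1.23 ± 0.18, and Col12a1 fell by 1.95 ± 0.18 by its brightest probe set, while its other probe sets (-0.40, adjusted p = 0.123, and -0.33, adjusted p = 0.283) did not pass. Col3a1 fell by 2.38 ± 0.53, a call lost without tamoxifen array 2 (adjusted p = 0.0702). Vcan rose by 2.22 ± 0.58, a call lost without tamoxifen array 1 (adjusted p = 0.0781), 2 (0.0883) or 3 (0.111). Its other probe sets gave 2.16, 1.85, 0.97 and 0.14, the last 2 not past the threshold (adjusted p = 0.148 and 0.381). Of 38 extracellular proteases and inhibitors 9 rose and 8 fell (10 and 10 adjusted over the list alone; list adjusted p = 0.773). The protease genes Adamts1 and Adamts9 rose by 2.33 ± 0.27 and 1.96 ± 0.19, the latter with a smaller rise of 0.43 by its other probe set. Plaur, the urokinase receptor gene, rose by 4.18 ± 0.27 by its brighter probe set, while the other one (0.34, adjusted p = 0.117) did not pass.

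None of the 5 lists of markers of other cell types passed in camera. In fry, which does not compare a list with other genes, the fibroblast (adjusted p = 0.0082) and macrophage (0.0182) lists passed as higher. Of 17 fibroblast markers, 4 rose and 3 fell (adjusted p = 0.396), and their median (0.19) and mean (-0.13) differed in sign. The 3 that fell were collagen genes that the matrix list also holds. Of these, Col1a2 fell by 0.46 ± 0.13, a call lost with the experiment as a block (adjusted p = 0.0530). It was also lost without vehicle array 2 (0.0833) or 3 (0.0782) or tamoxifen array 1 (0.0918), 2 (0.143) or 3 (0.119). Fbln1 rose by 1.61 ± 0.14, with its dimmer probe set at 0.11 (adjusted p = 0.448), and Postn was high in both groups, at 13.19 ± 0.65 and 13.58 ± 0.31. Of 20 macrophage markers 1 rose, Coro1a by 1.45 ± 0.25 (list adjusted p = 0.396). Of 11 endothelial markers 1 rose, Ramp2 by 1.29 ± 0.14, and 1 fell (list adjusted p = 0.716). None of 12 smooth muscle and pericyte markers (adjusted p = 0.711, median 0.10 and mean -0.04) and none of 13 lymphocyte and mast cell markers (adjusted p = 0.711) passed. These 5 lists had the same numbers adjusted over the list alone.

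Of 31 genes of DNA replication and S phase, 26 rose and none fell (28 and 0 adjusted over the list alone), with a median of 1.00. Gins1 rose by 2.45 ± 0.23, the replicative helicase gene Mcm5 by 2.44 ± 0.25 and the licensing factor gene Cdt1 by 2.24 ± 0.21. Of 33 genes of mitosis, 29 rose and none fell (32 and 0 adjusted over the list alone), with a median of 1.85. Ccna2 rose by 4.26 ± 0.46 from a low level of 3.72 ± 0.07, Ttk by 3.50 ± 0.35 (1.71 by its dimmer probe set) and Cdk1 by 3.40 ± 0.43. Both lists stood higher than other genes (camera, adjusted p = 2.99e-11 and 2.32e-13). Neither call held in camera with an estimated correlation (adjusted p = 0.457 with an estimated correlation, for each), which also rests on fewer degrees of freedom. The estimated correlation between members was 0.617 for S phase and 0.823 for mitosis. The share of the loss due to it was not tested. The ERK target list also went from 2.24e-13 to 0.0324, at an estimate of 0.00442. CDK inhibitors and p53 target genes did not move as a list: 5 of 23 rose and 5 fell (6 and 5 adjusted over the list alone; adjusted p = 0.868; median 0.04, mean -0.13, test direction higher). Cdkn1a, which encodes the CDK inhibitor p21, rose by 0.87 ± 0.16. The stress-response genes Gadd45a and Sesn1 fell by 2.71 ± 0.23 and fell by 2.42 ± 0.18, with -1.40 by the dimmer probe set of Sesn1.

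**Figure D4:**
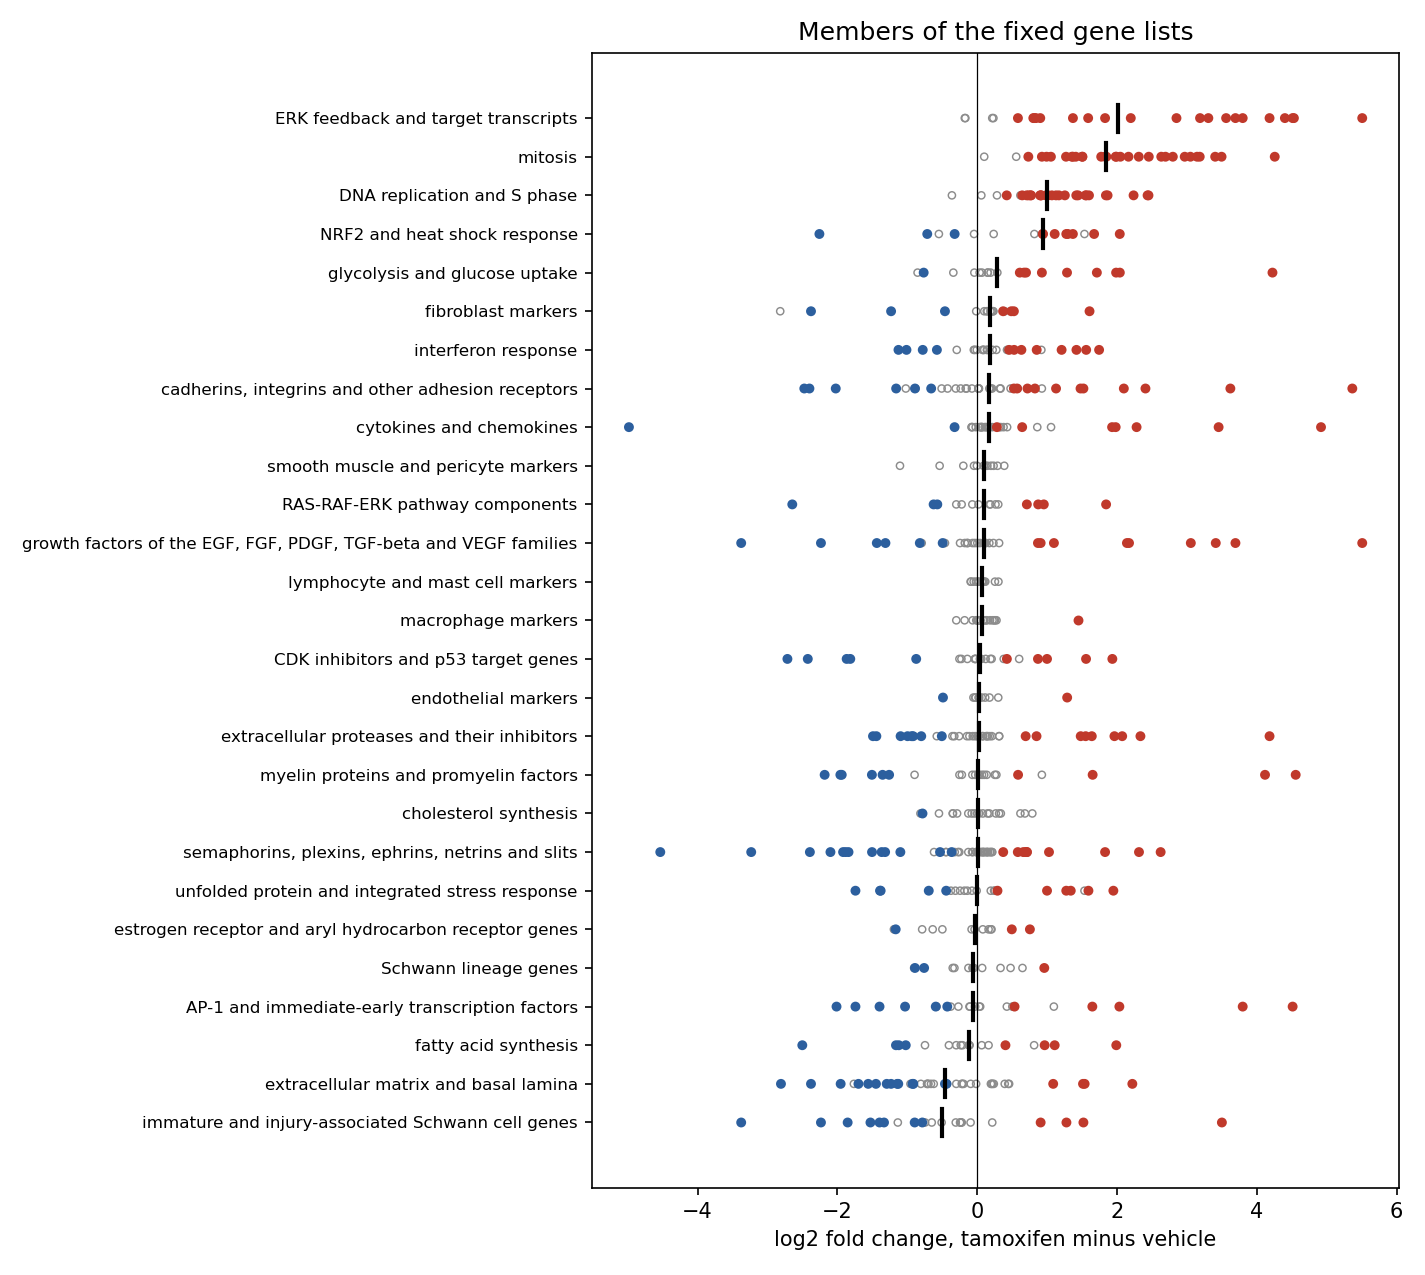
Log2 fold changes of the measured members of the 27 gene lists, with 1 point per gene, filled red or blue where it rose or fell (adjusted p under 0.05) and open where it did not pass, and a black bar at each list's median. The ERK target, mitosis and S phase lists have the 3 highest medians, at 2.01, 1.85 and 1.00.

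Genes of glycolysis and glucose uptake were higher as a list (9 of 19 rose and 1 fell; 10 and 1 adjusted over the list alone; adjusted p = 0.0125; adjusted p = 0.457 with an estimated correlation). The glucose transporter gene Slc2a3 rose by 4.22 ± 0.19, Pfkp by 2.04 ± 0.20 and Hk2 by 1.71 ± 0.31. Of 20 genes of cholesterol synthesis none rose and 1 fell (0 and 0 adjusted over the list alone; adjusted p = 0.868). That gene, Pmvk, fell by 0.79 ± 0.22, a call lost without vehicle array 1 (adjusted p = 0.0597) or 3 (0.0851) or tamoxifen array 1 (0.113) or 2 (0.118). Of 19 genes of fatty acid synthesis 4 rose and 4 fell (5 and 4 adjusted over the list alone; adjusted p = 0.867). Acsl4 rose by 1.99 ± 0.08, and the fatty acid desaturase genes Fads1 and Fads2 fell by 1.16 ± 0.14 and fell by 1.12 ± 0.18.

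Of 16 measured genes of the NRF2 and heat shock response, 8 rose and 3 fell (9 and 4 adjusted over the list alone). The adjusted p of the list was 0.0527, and with the experiment as a block it passed as higher (0.0166). It also passed without vehicle array 3 (adjusted p = 0.0241) or tamoxifen array 2 (0.0424). The same held with median centring (0.0285), quantile normalization (0.0364), cyclic loess (0.0468), the filter on dim probe sets (0.0478) and eBayes with trend and robust (0.0453). Fry, which does not compare a list with other genes, passed 18 of 27 lists, this one included (adjusted p = 0.00754). In camera with an estimated correlation the NRF2 and heat shock list did not pass (adjusted p = 0.457). The antioxidant genes Gclc, Hmox1 and Srxn1 rose by 2.04 ± 0.19, 1.67 ± 0.15 and 1.37 ± 0.11 (for Srxn1 another probe set rose by 1.79 and a dim one did not pass, at 0.12, adjusted p = 0.543), whereas the heat shock gene Hspa1a fell by 2.26 ± 0.11. Of 26 interferon response genes 8 rose and 4 fell (8 and 5 adjusted over the list alone; adjusted p = 0.0832, and 0.0452 without vehicle array 3; adjusted p = 0.457 with an estimated correlation). Usp18 rose by 1.74 ± 0.16 and Mx2 by 1.56 ± 0.12, while the dimmer probe set of Mx2 gave 0.09 (adjusted p = 0.572). In the unfolded protein and integrated stress response list, 6 of 23 rose and 5 fell (8 and 7 adjusted over the list alone; adjusted p = 0.752; median -0.01, mean 0.13). The amino acid synthesis genes Asns and Psat1 rose by 1.95 ± 0.15 and 1.59 ± 0.17, and Ppp1r15a fell by 1.39 ± 0.10. Of 13 estrogen receptor and aryl hydrocarbon receptor genes 2 rose and 1 fell, also when adjusted over the list alone, with a median of -0.04, a mean of -0.19 and a test direction of higher (adjusted p = 0.916).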

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

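The analyses without both arrays numbered 1 and with the 3' minus 5' covariate were chosen after seeing the data. The number of changed genes stayed within 1.5 times of 4433 under all alternatives but 2. With the unmoderated test 2235 genes changed (1133 higher, 1102 lower, 477 lower by at least 1 log2 unit) and 3672 probe sets (1957 higher, 1715 lower). With treat at a fold of 1.5, which asks for a larger change by construction, 883 genes changed (492 higher, 391 lower; 488 and 389 by at least 1 log2 unit) and 1448 probe sets (833 higher, 615 lower). These 2 tests give no value for lists. Leaving out 1 array gave 3097 to 4093 changed genes and 2668 to 3771 lower probe sets. With the replicate block 4730 genes and 8259 probe sets changed, 4148 of the 4433 genes kept their call, and 8 lists passed. The block changed no other list's call, and of the named genes it ended only that of Col1a2 (adjusted p = 0.0530). Lists past the threshold numbered 1 with an estimated correlation and 18 with fry, which does not compare a list with other genes. The other alternatives gave 6 to 8 lists. Scaling changed the share of higher calls from 44.6% to between 40.5% and 48.9%. Of 111 named genes past the threshold, 20 lost their call without 1 of the arrays, 34 with the unmoderated test and 32 with treat. With the unmoderated test those lost included Pmp22 (adjusted p = 0.0514), Mbp (0.0502), Itgb4 (0.0502), Cdh2 (0.0532) and Il33 (0.0738). An offset on linear values was not run, since the values were deposited as log2.

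Of the 4433 changed genes, 8 had the opposite sign with the mean of a gene's probe sets. Without probe sets of the suffix _s_at, _x_at or _a_at, 9 did. Among named genes and lists, directions turned only for results that did not pass in either setting, and the cause was not tested. Of single genes, leaving out 1 array gave ranges of -0.176 to 0.0678 for Araf, -0.0784 to 0.0717 for Acta2, -0.0578 to 0.0219 for Lck, -0.0105 to 0.241 for Laptm5, -1.04 to 0.177 for Tagln and -0.0400 to 0.0712 for Tpsb2. Median centring gave Tpsb2 -0.0232, quantile normalization Acta2 0.0557 and Tpsb2 -0.0172, cyclic loess Araf 0.0290 and Acta2 0.0699, and leaving out both arrays numbered 1 gave Lck 0.00325. Among lists the adjusted p values with the other direction were, for estrogen and aryl hydrocarbon receptor genes, 0.934 (block), 0.988 (quantile), 0.960 (cyclic loess), 0.847 (dim filter), 0.951 (array weights), 0.767 (without both arrays numbered 1) and 0.860 (covariate). For cholesterol synthesis they were 0.897 (array weights), 0.986 (without both arrays numbered 1) and 0.852 (covariate), and for myelin genes 0.986 and 0.985 in the last 2 of these settings. With the filter on dim probe sets they were 0.976 for Schwann lineage genes, 0.861 for fibroblast markers and 0.913 for smooth muscle markers, and with fry 0.683 for fatty acid synthesis and 0.901 for CDK inhibitors and p53 targets. Leaving out 1 array turned the direction of some lists, and over all 6 arrays left out in turn the adjusted p ranged from 0.748 to 0.938 for the estrogen and aryl hydrocarbon receptor list, 0.0749 to 0.839 for cholesterol synthesis, 0.721 to 0.971 for myelin genes, 0.665 to 0.938 for Schwann lineage genes and 0.613 to 0.986 for fatty acid synthesis.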

Other observations

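The gene families below were defined by shared symbol roots after the data were seen, and the tests on the 5' signal, on fibroblasts and on the splits of genes and probe sets were also chosen after their results were seen. Of 260 families with at least 8 measured genes, 25 passed camera at its preset correlation, 15 higher and 10 lower after tamoxifen, and 0 passed with an estimated correlation (adjusted p = 0.891 for each of those named here as having passed). With the experiment as a block 22 of the 25 passed, and the calls of Fbxo (adjusted p = 0.0625), Cdca (0.0553) and Vps (0.0552) ended. The Ift family, whose proteins carry cargo along the primary cilium, had the smallest p: 12 of 17 genes fell and 0 rose (median -0.93, adjusted p = 2.33e-04). Ift70b fell by 2.59 ± 0.18 (SE, n = 3 arrays per group), Ift81 fell by 1.47 ± 0.24 and Ift122 fell by 1.34 ± 0.16. The median was -0.84 with cyclic loess and -0.96 with each array centred, and lay between -0.94 and -0.78 when 1 array was left out. The Cog family of Golgi tethering proteins had 6 of 8 genes lower (median -0.57, adjusted p = 0.00789), and of 220 genes of the Zfp zinc finger family 81 fell and 13 rose (median -0.29, adjusted p = 2.64e-04).

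The higher families included Utp, Polr and Nop, picked after the data were seen, and none of these calls held with an estimated correlation (adjusted p = 0.891 for each). Of 10 Utp genes, which act in assembly of the small ribosomal subunit, 9 rose (median 0.76, adjusted p = 0.00225). Of 29 RNA polymerase subunit genes (Polr) 15 rose and 1 fell (adjusted p = 0.00746), with Polr1e rising by 2.07 ± 0.27. Of 8 Nop genes 5 rose and 1 fell (adjusted p = 0.0168), Nop16 by 1.74 ± 0.15 and Nop58 by 1.66 ± 0.13. The Exosc family of RNA exosome subunits also passed (6 of 9 rose and 0 fell, adjusted p = 0.0248), whereas Nol (4 of 10 rose and 2 fell, adjusted p = 0.486), Med (0.299), Taf (0.609) and Gtf (0.907) did not. The example genes here and in the family account above were chosen after their values were seen. None of Ift, Cog, Zfp, Utp, Polr and Nop changed the sign of its median when each array was centred or when quantile or cyclic loess normalization was applied again.

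A hypothesis is that ribosome assembly genes in general were higher after tamoxifen. A list of other such genes was written before their values were seen. Of 50 measured, 44 rose and 1 fell, with a median of 1.08 (camera p = 1.44e-18 at the preset correlation), as the hypothesis predicts. Camera with an estimated correlation (0.704 between members), which also uses fewer degrees of freedom, gave p = 0.145. The list still holds genes that act with the Utp and Nop proteins under other symbols, among them Wdr36, Heatr1, Pwp2 and Fbl. It is therefore not independent of the families that prompted the hypothesis. Nhp2, Wdr12 and Gar1 had the largest rises, at 2.06, 1.99 and 1.94, and Surf6 fell by 0.79.

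Cilium genes may be lower in general, a second hypothesis tested on a list written before its values were seen. Of 42 measured cilium genes outside the Ift family by symbol, 24 fell and 1 rose (median -0.53, camera p = 5.03e-07), with p = 0.0837 with an estimated correlation. The list still holds genes of the same cargo transport under other symbols (Wdr19, Wdr35, Traf3ip1 and Cluap1). Motor subunits of that transport are also on it (Dync2h1, Dync2li1, Kif3a, Kif3b and Kifap3), so the list is not independent of the Ift family. Wdr19 fell by 1.86 ± 0.17 and Bbs2 fell by 1.55 ± 0.12, while Ahi1 rose by 1.62 ± 0.24. A technical candidate for the lower Ift family is the unequal 5' signal of the arrays. With the 3' minus 5' difference as a covariate the family's median was -0.79. The bound set beforehand against this explanation was -0.6, and the median lay beyond it by more than its jackknife standard error over arrays (0.124), a measure of spread chosen after the values were seen. This argues against the unequal 5' signal as the whole cause. A share of it stays open, since a fit to the family median per array gave -0.75 with a standard error of 0.159, so that the bound lies within 1 standard error. Without the array of weakest 5' signal the median was -0.81.

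The weak 5' signal of the first vehicle array could come from degraded cell RNA or from cDNA synthesis and amplification. Bacterial transcripts added to the RNA showed a 3' minus 5' difference of 1.81 there, 0.68 above the highest of the other 5 arrays, whose whole range was 0.316. Degradation of the cell RNA before these transcripts were added would give no such excess, so the value speaks against it as the whole cause, while a weaker cDNA synthesis or amplification is in line with it. The hybridisation controls, added later, were also slightly above the other arrays (0.188 against 0.101 to 0.163), by less than the range of those arrays. No biological explanation was tested.

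The lower matrix transcripts after tamoxifen could reflect fewer fibroblasts in the cultures. Of 12 fibroblast markers outside the matrix list, only 3 lay at least 1 log2 unit above the dimmest 25% of probe sets in vehicle, and levels near background exclude nothing. Dcn and Lum had vehicle means of 4.05 and 3.44, below the upper bound of those dimmest probe sets (4.79), and Pdgfra and Thy1, at 4.90 and 5.0, were little above it. The level that a given share of fibroblasts would give with these probe sets is not known, and levels of different probe sets were not compared. The median change of these 3 was 0.37, from Fbln1 (1.61), Pi16 (0.37) and Mfap5 (-2.82, with a vehicle SD of 2.51), which go both ways. They are too few to decide, so the explanation stays open. A change within the Schwann cells stays open, as does an effect of tamoxifen itself.

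The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4433 genes and 7578 probe sets, and the highest of the others gave 0 for both, so 1 of 10 splits reached each number. Every other split mixes both treatments on each side, so the treatment difference adds to the spread within sides. The counts of 0 are therefore no measure of false calls. For gene lists the real split gave 6, and 2 of 10 splits gave as many. The highest other gave 9, from vehicle 1, vehicle 2 and tamoxifen 2 against the rest, a split that parts only 1 of the 3 same-number pairs. Among the 4 splits that part all 3 pairs, the other 3 gave 0 genes and 1, 3 and 4 lists.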
